A study of Mus musculus with 10 samples.

How the data were processed

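The series used 3'-end sequencing of polyadenylated RNA from cultured mouse mammary tumour lines of the 4T1 family. There were 10 libraries in 5 groups of 2: 67NR and 168FARN, labelled non-invasive, 4T07 and 4T1, labelled invasive, and 4T1 cells given an antisense morpholino against the U1 small nuclear RNA (4T1-U1-ASO). The series design calls the first 2 lines non-metastatic and the others metastatic. It names a mock-transfected control for the antisense oligonucleotide, while the labels of the 4T1 libraries give no treatment. Per the labels' protocols, poly(A)+ RNA was purified from 5 µg of total RNA, fragmented and reverse transcribed with anchored oligo-dT. The libraries were amplified by 13 PCR cycles, selected for fragments of 200 to 300 bp and read as 50-nt single ends. The morpholino was given with a delivery reagent at 6 µl/mL. No label says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

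The submitters' processing notes name Bowtie2 2.2.5, SAMtools 1.1, bedtools 2.17.0, DESeq2 1.4.5 and the mouse build mm9, without saying which step each served. The peak lists were deposited per library by the authors, as filtered lists with a whole-number read count per peak. What the filter removed is not given in the sources used here. The deposited comparison tables list intronic polyadenylation (IPA) sites. An IPA site is a 3' end inside an intron, and its use is compared with that of the last exon of the same gene. Per the file headers, each row holds a log2 fold change with its standard error, a test statistic or score, a p-value and an adjusted p-value. All are the authors' own, and only sites with an adjusted p of at most 0.1 are listed. The tables also give, per the file headers, a normalized read signal for the site and for the last exon in each of the 4 libraries of a comparison. Values set side by side across tables come from separate normalizations. Because those signals were deposited to 2 decimals, the value of 1 read could be found in every column, and 100% of values came out whole within a tolerance of 0.1 read. The reads recovered in this way are used below. Recovered reads equalled the same library's own peak list at 53.1% to 80.4% of the sites compared, and the other replicate's list at 3.92% to 24.9%.

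IPA usage is given as the percentage of IPA reads among IPA and last-exon reads of a library, as mean ± SD over 2 libraries. Library scaling cancels in it. Deposited fold changes are written as the first-named group minus the second, where the first is the metastatic line or the U1-ASO group; the deposited sign was turned for the tables against 67NR. The sign matched the normalized values at all 2311 listed sites, and positions are 1-based on mm9 as in the tables. No mm9 annotation was used here, so peaks outside the tables were not assigned to genes and IPA sites are called intronic on the authors' word. For that reason the planned tests of gene counts, the gene-set tests on them and the single fit over 10 libraries were not run. The count and direction of sites in the authors' deposited tables are the main result of each comparison, the planned fallback. This fallback, the rule for named sites, the gene lists and the first set of alternative analyses were fixed before the data were examined. Of 1453 gene symbols, 1447 matched a current symbol or a unique synonym in the RefSeq gene table of GRCm38, used for names only.

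The recovered reads were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, the authors' size factors, Benjamini-Hochberg adjusted p under 0.05), chosen after seeing the data. TMM had been planned as the scaling and became an alternative. One model tested IPA relative to the last exon; separate models tested IPA reads and last-exon reads alone. All 3 ran on listed sites only, so adjustment covers sites already selected by the authors and such p-values are not independent evidence. The model of IPA relative to the last exon was tested on simulated data made from the real means with a dispersion of 0.05. The separate models of IPA reads and last-exon reads were not tested in this way. Among the 1561 sites of the U1-ASO comparison, 81.8% of sites changed by 3 log2 units and 50.7% of those changed by 2 were recovered, with 6 calls among 1361 unchanged sites. DESeq2 1.42.0 was an alternative. Other alternatives were TMM scaling, no low-count filter, a replicate block, leaving out each library, stricter deposited thresholds and peaks called in both replicates. A library block, scaling by peak-list read totals, peak numbers at equal depth, comparisons without 67NR the test of direction among shared sites, its repeat with each site of the second table counted once, the overlap tests against the sites of the line tables, the 2 further tests of falls at the site and the differences between lines on recovered reads were added after seeing the data.

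The named sites are, in each comparison, the 6 sites higher and the 6 lower, 1 per gene, with the largest deposited fold change and a peak in both replicates of the group with higher usage. Up to 8 further genes of the fixed lists follow by smallest adjusted p, at most 2 per list. Where a library's peak list lacks the chromosome, or that of 67NR replicate 2 ends before the site, a recovered read at the site stood in for a peak. Of the 21 gene lists, 1 is not reported here, and neither are a few named genes, so the sites named are not always those with the largest change. The other 20 lists were: U1 snRNP, cleavage and polyadenylation factors, SR and hnRNP splicing factors, transcription elongation factors, DNA damage response and repair, p53 targets, receptor tyrosine kinases, epithelial genes, mesenchymal and EMT genes, fibroblast and matrix genes, leukocyte markers, endothelial markers, integrins and focal adhesion, matrix proteases and inhibitors, TGF-beta and BMP signalling, Wnt, Notch and Hippo signalling, drug transport and drug targets, cell cycle and replication, heat shock and unfolded protein response, and interferon response. List membership was tested with a two-sided Fisher's exact test against all 1453 genes with a site in any table. Overlaps were tested only between comparisons that share no library, against the 2010 distinct sites of all tables. The plan named genes for this total, and the 1453 genes serve the matching by symbol. In that matching a gene with sites in both directions of a table counts once per direction. Sites of 1 gene are not independent in these tests. Shares carry exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 reads. Reads were PCR-amplified with no molecular identifiers named in the labels, so intervals and limits cover counting error only.

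Depth was read from the peak lists, which held 1427728 to 3347776 reads per library. The list of 67NR replicate 2 is incomplete. It covers 10 chromosomes and ends within chromosome 18. It consists of 2 blocks with 9496 and 38155 peaks that each run through the same 10 chromosomes, with 20.8% and 62.5% peaks of 1 read. They may be 2 lists joined, so peak numbers of this library are not comparable with the others. Peak numbers were therefore compared on the 9 chromosomes that every list covers, at 1101154 reads per library. The table reads of this library cover all chromosomes. Other tests were computed in Python 3.11.15 with scipy 1.17.1.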

Results

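Polyadenylated 3' ends were measured in 10 libraries of mouse mammary tumour cells, 2 for each of 5 groups. The lines 67NR, 168FARN, 4T07 and 4T1 form a series that the study divides by metastatic ability, with 67NR and 168FARN non-metastatic and 4T07 and 4T1 metastatic. The last group was 4T1 cells given an antisense morpholino against U1, the small nuclear RNA that recognises 5' splice sites and protects transcripts from premature cleavage and polyadenylation. U1 RNA itself carries no poly(A) tail, so its level was not measured here. Peak lists held 2499475 and 2795040 reads for 4T1, 2596503 and 2643219 for 4T1-U1-ASO, 3347776 and 1427728 for 67NR, 2753926 and 3106253 for 4T07, and 2875561 and 3024906 for 168FARN. The lower 67NR value comes from the list of replicate 2, which is incomplete and runs through the same 10 chromosomes in each of 2 blocks. Between 36.3% and 51.5% of the peaks of a library overlapped a peak of its replicate by at least 1 bp, and these peaks held 92.8% to 95.5% of its reads. Overlap with libraries of other groups reached 52.7% and was in part higher than with the replicate in 4T1, 4T07 and 168FARN, so it does not measure agreement within a group.

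The first question was which intronic polyadenylation (IPA) sites differ in use between metastatic and non-metastatic lines. In 4T1 against 67NR, the largest fold change in the authors' deposited table was at Spint2, an inhibitor of membrane serine proteases. Its site on chromosome 7, 30051548 to 30051812, on the minus strand, made up 0.259% ± 0.0726 of IPA and last-exon reads in 4T1 and 83.3% ± 23.6 in 67NR (SD, n = 2). The last exon of Spint2 had 963 and 965 reads in 4T1 and 5 and 0 in 67NR, while the site had 2 and 3 reads against 10 and 10. Usage was also lower in 4T1 at Dhx40, a DEAH-box helicase gene, with 2.83% ± 4.00 against 91.0% ± 6.14 (SD, n = 2). Higher usage in 4T1 was found at Cpeb3, which encodes a binder of cytoplasmic polyadenylation elements, with 88.7% ± 2.53 against 32.7% ± 16.5 (SD, n = 2).

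Of 122 sites in 117 genes that the authors' deposited table lists for this comparison, 29 were used more in 4T1 and 93 more in 67NR, so 76.2% were higher in 67NR (Clopper-Pearson 95% interval 67.7% to 83.5%). The log2 fold changes in the authors' deposited table were -5.89 for Spint2, -3.23 for Dhx40, -2.95 for Gpr126, -2.84 for Cblc and -2.83 for Slc25a13. Gpr126 is an adhesion G protein-coupled receptor, Cblc a ubiquitin ligase of the Cbl family and Slc25a13 a mitochondrial aspartate-glutamate carrier. No last-exon reads of Gpr126 or Cblc were counted in 67NR, so usage there was 100% from 9 and 8 IPA reads for Gpr126 and 16 and 13 for Cblc. Among sites higher in 4T1, the authors' deposited table gives 2.88 for AI506816, 2.68 for Tmem167, 2.08 for Snrnp35, 2.05 for Cpeb3, 2.03 for Trps1 and 1.94 for Prickle2. Snrnp35 encodes a protein of the minor spliceosome, Trps1 a GATA-type repressor and Prickle2 a planar cell polarity protein. Tmem167 usage was 19.1% ± 0.772 in 4T1 and 2.66% ± 0.487 in 67NR (SD, n = 2). AI506816 had no IPA read among 499 last-exon reads in 67NR, which allows a usage of up to 0.601%, against 12.6% ± 0.941 in 4T1 (SD, n = 2).

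Among the gene lists, 1 member each was found in this comparison for cell cycle (Ccnb1), mesenchymal genes (Twist2), Wnt, Notch and Hippo signalling (Ctnnb1) and epithelial genes (Spint2). Ccnb1, which encodes cyclin B1, fell from 5.10% ± 0.245 in 67NR to 1.06% ± 0.460 in 4T1 (SD, n = 2). Twist2, a transcription factor of mesenchymal cells, had 4 and 7 IPA reads with 2 and 0 last-exon reads in 4T1, against 3 and 6 IPA reads with 74 and 54 last-exon reads in 67NR. Usage of the site in Ctnnb1, beta-catenin, was low in both lines, at 0.0270% ± 0.0382 against 0.371% ± 0.00860 (SD, n = 2). Reads at the site itself fell in 63 of the 93 sites lower in 4T1 and rose in 0, and 26 of the 93 passed on the last exon alone (edgeR quasi-likelihood test). At an adjusted p of at most 0.01, the authors' deposited table keeps 36 of the 122 sites.

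**Figure D1:**
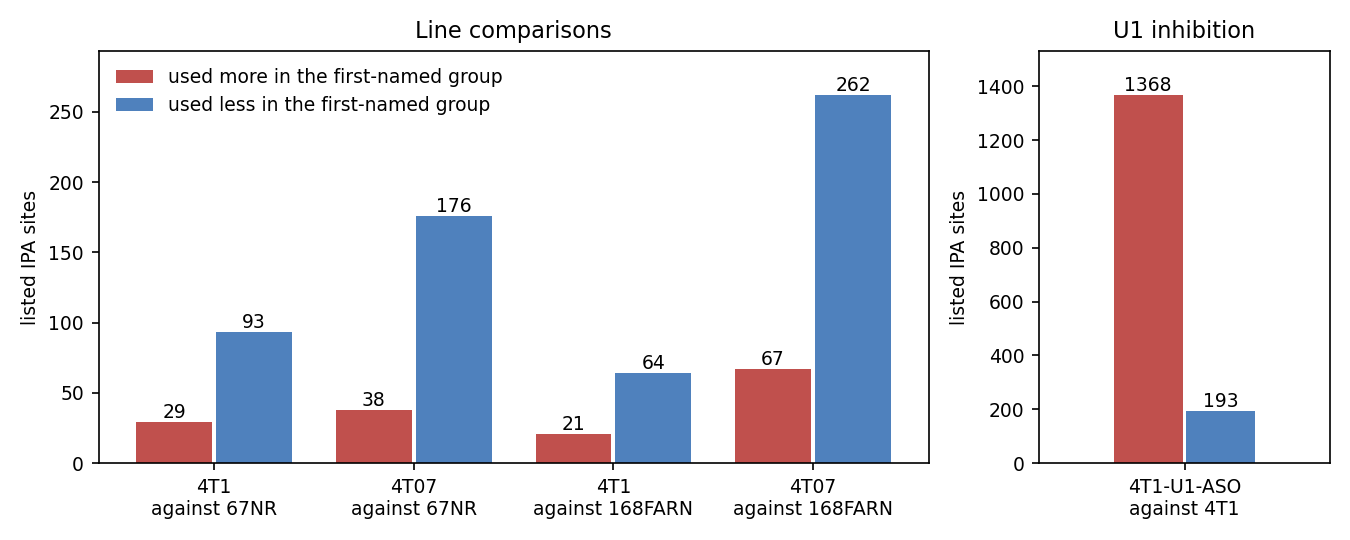
Number of IPA sites listed in the authors' deposited tables per comparison, with bars for sites used more or less in the first-named group. In the 4 comparisons of lines, sites used less in the metastatic line were the more numerous (93, 176, 64 and 262), and under U1-ASO sites used more were (1368).

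In 4T07 against 67NR, Sec23b, a coat protein of vesicles leaving the endoplasmic reticulum, was used at its intronic site at 1.72% ± 0.275 in 4T07 and 38.1% ± 1.35 in 67NR (SD, n = 2). Its IPA reads were 5 and 7 against 167 and 144, and its last-exon reads 322 and 358 against 261 and 244, a rise of 0.62 in log2 (edgeR quasi-likelihood test, adjusted p = 0.00434). Rock2, a serine/threonine kinase, was used at 27.5% ± 7.66 in 4T07 and 83.4% ± 9.88 in 67NR (SD, n = 2), with 28 and 48 IPA reads against 613 and 662. In the other direction, Hmga2, an architectural chromatin protein, reached 5.40% ± 0.462 in 4T07 and 0.587% ± 0.147 in 67NR (SD, n = 2). Trps1 reached 26.8% ± 1.19 in 4T07 and 0.412% ± 0.583 in 67NR (SD, n = 2), at a site on chromosome 15 from 50554556 to 50556845.

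This comparison held 214 sites in 200 genes in the authors' deposited table, 38 higher and 176 lower in 4T07, and 82.2% were higher in 67NR (Clopper-Pearson 95% interval 76.5% to 87.1%). Fold changes in the authors' deposited table were -6.27 for Spint2, -5.74 for Dhx40, -4.17 for Sec23b, -3.93 for As3mt and -3.85 for Camk1d on the log2 scale. As3mt, an arsenite methyltransferase, had 0 IPA reads among 191 last-exon reads in 4T07, a usage of up to 1.57%, against 93.8% ± 8.84 in 67NR (SD, n = 2). Camk1d, a calcium-dependent kinase, had 39 and 36 IPA reads in 4T07 and 32 and 25 in 67NR, and its last-exon reads were 135 and 132 against 1 and 0. The site in 4931406C07Rik was used at 1.92% ± 0.879 in 4T07 and 55.2% ± 1.24 in 67NR (SD, n = 2). Otud7a, a deubiquitinase, had 21 and 32 IPA reads and no last-exon reads in 4T07, while usage was 39.9% ± 14.3 in 67NR (SD, n = 2). Celf4, an RNA-binding protein, was used at 4.51% ± 1.12 in 4T07 (SD, n = 2), and 0 reads among 482 last-exon reads in 67NR allow up to 0.622%.

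Some lists had several genes here, although none passed the test. Cell cycle genes were 3 (Ccnb1, Ccnd3 and E2f1), all lower in 4T07, with an expected 1.24 (two-sided Fisher's exact test, p = 0.115, adjusted p = 0.804). E2f1, a transcription factor of S-phase entry, was used at 0.168% ± 0.0861 against 2.37% ± 0.930 and Ccnb1 at 1.03% ± 0.808 against 5.10% ± 0.245 (SD, n = 2). Mesenchymal genes were also 3, with Axl and Sparc lower and Twist2 higher in 4T07, at the same expected number and p. Sparc, a matrix glycoprotein, had 0 IPA reads among 14018 last-exon reads in 4T07, and 5 and 14 in 67NR. Without 4T07 replicate 1, 4T07 replicate 2 or 67NR replicate 2 the fitted log2 change was -5.15, -5.25 and -4.14, against -5.17 with all libraries, but no longer passed (edgeR quasi-likelihood test, adjusted p = 0.0677, 0.0764 and 0.115). Tia1, which helps U1 bind weak 5' splice sites, was used at 2.08% ± 0.309 in 4T07 and 12.4% ± 2.80 in 67NR, and Plaur, the urokinase receptor, at 0.420% ± 0.331 against 2.36% ± 0.283 (SD, n = 2). Ptk2, focal adhesion kinase, was the 1 listed gene of the integrin list. Reads at the site itself fell in 104 of the 176 lower sites and rose in 1, and 52 passed on the last exon alone (edgeR quasi-likelihood test). The authors' deposited table keeps 110 sites at an adjusted p of at most 0.01.

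In 4T1 against 168FARN, Gosr2, a SNARE protein of the Golgi, was used less at its intronic site on chromosome 11 from 103544527 to 103545247, with 0.413% ± 0.584 in 4T1 and 43.3% ± 5.42 in 168FARN (SD, n = 2). IPA reads were 1 and 0 against 81 and 92, with 120 and 117 against 124 and 103 last-exon reads. Tpm1, a tropomyosin of actin filaments, was used at 0.817% ± 0.322 in 4T1 and 7.40% ± 0.794 in 168FARN (SD, n = 2). Wdr33, a subunit that reads the polyadenylation signal, was used at 21.1% ± 7.88 against 49.2% ± 2.09, and Ccnd2, cyclin D2, at 2.74% ± 0.206 against 9.09% ± 1.23 (SD, n = 2). Cpeb3 was higher in 4T1, with 88.7% ± 2.53 against 19.8% ± 12.3 (SD, n = 2).

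The authors' deposited table lists 85 sites in 79 genes for this comparison, 21 higher and 64 lower in 4T1, and 75.3% were higher in 168FARN (Clopper-Pearson 95% interval 64.8% to 84.0%). Spint2 had the most negative fold change in the authors' deposited table, with a log2 value of -6.00. No Spint2 last-exon read was counted in 168FARN, against 963 and 965 in 4T1. Usage of Dhx40 was 2.83% ± 4.00 in 4T1 and 96.5% ± 0.686 in 168FARN, and that of Gpr126 was 7.43% ± 5.57 against 93.8% ± 8.84 (SD, n = 2). Camk1d was used at 42.5% ± 21.7 in 4T1, and 168FARN had 37 and 33 IPA reads with no last-exon reads. Among higher sites, Slc35b2, a Golgi sulfate-donor transporter, was used at 5.98% ± 1.72 against 0.137% ± 0.194 and Ngef, a guanine nucleotide exchange factor, at 52.5% ± 10.6 against 1.8% ± 1.15 (SD, n = 2). Ngef had 9 and 9 IPA reads in 4T1 and 7 and 2 in 168FARN, and its last-exon reads were 11 and 6 against 261 and 202. Nlrp4e had 5 and 13 IPA reads and no last-exon reads in 4T1, and was used at 8.71% ± 1.15 in 168FARN (SD, n = 2). AI506816 had 0 IPA reads among 244 last-exon reads in 168FARN, which allows up to 1.23%.

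Twist2 and Prrx1, transcription factors of the mesenchymal list, were the 2 list members used more in 4T1 (two-sided Fisher's exact test in that direction, p = 0.00552, adjusted p = 0.116). Twist2 had 2 and 0 last-exon reads in 4T1 and 309 and 293 in 168FARN, with 4 and 7 against 7 and 5 IPA reads. Prrx1 rested on 0 and 1 IPA reads in 4T1, and without 4T1 replicate 2 its adjusted p was 0.929 (edgeR quasi-likelihood test). Ccnk, the cyclin of elongation-promoting kinases, was used at 0.130% ± 0.184 against 2.45% ± 1.31 (SD, n = 2). Reads at the site itself fell in 32 of the 64 lower sites and rose in 3, and 23 passed on the last exon alone (edgeR quasi-likelihood test). At an adjusted p of at most 0.01, 36 sites stay in the authors' deposited table.

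In 4T07 against 168FARN, Rock2, Atm and Wdr33 were used less at their intronic sites in 4T07, and Trps1 and Abcb10 more. Rock2 usage was 27.5% ± 7.66 in 4T07 and 83.4% ± 3.13 in 168FARN at the site on chromosome 12 from 16929810 to 16929888 (SD, n = 2). Atm, the kinase that signals double-strand breaks, was used at 5.73% ± 1.03 against 48.7% ± 7.25, on 2 and 2 IPA reads against 14 and 17 (SD, n = 2). Abcb10, a mitochondrial transporter, was used at 26.6% ± 1.55 in 4T07 and 1.58% ± 0.869 in 168FARN (SD, n = 2). Trps1 had 132 and 145 IPA reads in 4T07 and 0 in 168FARN, where 174 last-exon reads allow up to 1.72%.

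This was the longest list among the lines, with 329 sites in 284 genes in the authors' deposited table, 67 higher and 262 lower in 4T07. The share higher in 168FARN was 79.6% (Clopper-Pearson 95% interval 74.9% to 83.9%). Log2 fold changes of -6.63 for Dhx40, -6.50 for Spint2, -4.75 for Camk1d and -3.84 for Gpr126 stand in the authors' deposited table. Gosr2 had 0 IPA reads among 184 last-exon reads in 4T07, which allows up to 1.63%, and Uggt1, a folding sensor of the endoplasmic reticulum, 0 among 3183, which allows up to 0.0943%. In 168FARN, Gosr2 was used at 43.3% ± 5.42 and Uggt1 at 1.42% ± 0.148 (SD, n = 2). AI506816 was used at 32.2% ± 4.59 and Snrnp35 at 12.4% ± 3.04 in 4T07 (SD, n = 2). Snrnp35 had 0 IPA reads among 366 last-exon reads in 168FARN, which allows up to 0.820%. Nlrp4e had 18 and 14 IPA reads and no last-exon reads in 4T07. For Ngef, usage was 24.6% ± 12.4 in 4T07 and 1.8% ± 1.15 in 168FARN (SD, n = 2), and without 4T07 replicate 1 its fitted log2 change was 3.29, against 3.98 with all libraries, with adjusted p = 0.0554 (edgeR quasi-likelihood test).

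DNA repair genes were 3 in this comparison, all lower in 4T07 (Atm, Palb2 and Rad51c), with an expected 1.95 (two-sided Fisher's exact test, p = 0.421). Palb2, a partner of Brca proteins, was used at 55.0% ± 3.36 against 81.9% ± 3.57, and Rad51c, a recombination factor, at 14.3% ± 3.14 against 38.4% ± 4.48 (SD, n = 2). Cleavage and polyadenylation factors were also 3, with Wdr33 and Papola lower and Ssu72 higher in 4T07 (expected 2.15, p = 0.458, exact test). Wdr33 was used at 27.5% ± 1.97 against 49.2% ± 2.09, and Papola, the poly(A) polymerase, at 6.45% ± 0.963 against 15.3% ± 2.81 (SD, n = 2). Ssu72, a phosphatase of RNA polymerase, was used at 1.75% ± 0.105 in 4T07 (SD, n = 2), with 0 IPA reads among 896 last-exon reads in 168FARN. Cell cycle genes were Ccnd2 and E2f1, and Hippo pathway genes were Tead1, at 0.813% ± 0.751 against 4.71% ± 0.711, and Wwtr1, at 0.239% ± 0.0589 against 1.03% ± 0.134 (SD, n = 2). Plaur was used at 1.15% ± 0.705 against 5.88% ± 1.57 (SD, n = 2), at a different site from the one listed against 67NR. Tra2a was the 1 member of the SR and hnRNP list, higher in 4T07. Reads at the site itself fell in 131 of the 262 lower sites and rose in 16, and 85 passed on the last exon alone (edgeR quasi-likelihood test). The authors' deposited table keeps 138 sites at an adjusted p of at most 0.01.

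Across the 4 comparisons of lines, 520 distinct sites were listed, and 13 stood in all 4. Usage was lower in both metastatic lines at 9 of the 13, in Camk1d, Dhx40, Exd2, Gpr126, Hip1, Slc25a13, Spint2, Tpm1 and Tpx2, and higher at 4, in AI506816, Snrnp35, Trps1 and Twist2. For Twist2 the difference lies in the last exon: 4T07 had 2 and 1 IPA reads and no last-exon reads, against 3 and 6 IPA reads in 67NR and 7 and 5 in 168FARN. At Gpr126 and Camk1d it also lay mostly in the last exon. Mean last-exon reads in 67NR, 168FARN, 4T07 and 4T1 were 0, 0.5, 109.5 and 122 for Gpr126 and 0.5, 0, 133.5 and 37.5 for Camk1d. Spint2 (2.5, 0, 789.5 and 964) and Dhx40 (4, 1, 177.5 and 75.5) also had few in the non-metastatic lines. The IPA reads themselves were fewer in both metastatic lines at Exd2, Hip1, Slc25a13, Tpm1 and Tpx2, and also at Dhx40 and Spint2. Dhx40 had 39 and 41 IPA reads in 67NR and 24 and 32 in 168FARN, against 0 and 3 in 4T07 and 3 and 0 in 4T1. Spint2 had 10 and 10 in 67NR and 7 and 6 in 168FARN, against 2 and 2 in 4T07 and 2 and 3 in 4T1. Tpx2, a spindle assembly factor, was used at 6.51% ± 2.31 in 67NR and 8.74% ± 1.83 in 168FARN, against 0.236% ± 0.334 in 4T07 and 1.5% ± 0.067 in 4T1 (SD, n = 2). Hip1, a clathrin adaptor, was used at 14.2% ± 0.595 and 5.68% ± 2.38 in the non-metastatic lines against 1.36% ± 0.0860 in 4T07 and 0.844% ± 0.559 in 4T1 (SD, n = 2). Exd2, an exonuclease, was used at 33.6% ± 0.399 and 23.7% ± 1.8 against 0.962% ± 1.36 and 3.12% ± 1.93 (SD, n = 2). These comparisons share libraries, so the number found in all 4 was not tested.

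**Figure D2:**
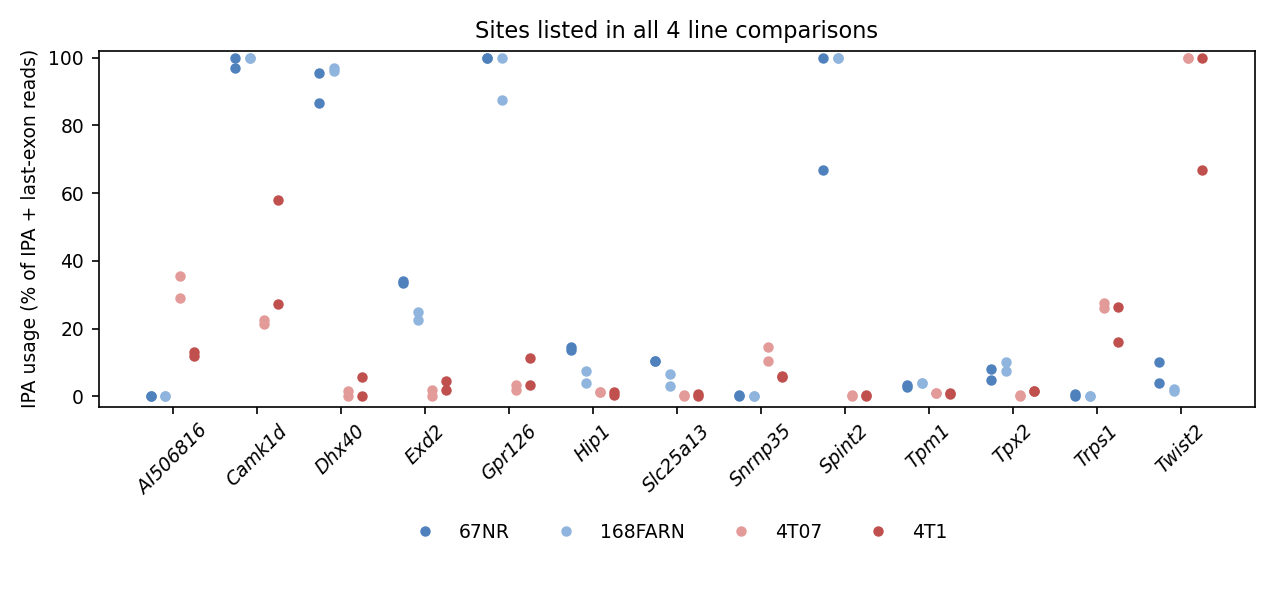
IPA usage in percent of IPA and last-exon reads, per library, for the 13 sites listed in all 4 comparisons of lines. Points are libraries of 67NR, 168FARN, 4T07 and 4T1; Dhx40 lies at 91.0% and 96.5% on average in the non-metastatic lines and at 0.761% and 2.83% in 4T07 and 4T1.

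Pairs of comparisons without a common library were tested for shared sites. 4T1 against 67NR and 4T07 against 168FARN shared 37 sites, and 30 changed in the same direction, with 22.8 expected from the margins (two-sided Fisher's exact test of direction, adjusted p = 0.00706 over 12 tests). Among them, 24 were lower in both, including Ldhb, Sec23b, Parn and Pde4d, with 12.1 expected on the background of 2010 sites (Fisher's exact test, adjusted p = 0.00140), and 6 were higher in both, with 0.970 expected (adjusted p = 0.000852, exact test). The 6 lie in AI506816, Padi2, Snrnp35, Twist2 and, at 2 sites, Trps1. 4T07 against 67NR and 4T1 against 168FARN shared 21 sites, of which 11 were lower in both (5.60 expected, adjusted p = 0.0308) and 4 higher in both (0.400 expected, adjusted p = 0.00124, Fisher's exact tests). In this pair 15 of 21 had the same direction, which did not pass (Fisher's exact test, adjusted p = 0.175). The excess in number depends on that background, most of which comes from the U1-ASO table. Against the 520 sites of the line tables, 46.9 and 21.7 were expected lower in both (adjusted p = 9.96e-07 and 0.00824, a deficit), and 3.74 and 1.53 higher in both (adjusted p = 0.247 and 0.0882, Fisher's exact tests). The number shared therefore decides nothing, and the direction test uses no background. When genes were matched by symbol, the direction test gave adjusted p = 0.131 for the first pair and 0.0311 for the second (Fisher's exact tests).

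The second question was how blocking U1 changes IPA use in 4T1 cells. Luc7l2, a protein associated with the U1 particle, rose from 0.893% ± 1.26 in 4T1 to 43.0% ± 0.546 in 4T1-U1-ASO, and Tra2a, a splicing activator, from 1.33% ± 1.88 to 35.4% ± 2.74 (SD, n = 2). Other sites were used less, with Dancr, a long noncoding RNA, falling from 73.2% ± 9.29 to 9.31% ± 0.306 and Tmem167 from 19.2% ± 0.683 to 0.787% ± 0.535 (SD, n = 2). Uchl5, a deubiquitinase of the proteasome, fell from 30.4% ± 11.1 to 2.26% ± 0.00580 (SD, n = 2).

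The authors' deposited table lists 1561 sites in 1131 genes, 1368 higher and 193 lower in 4T1-U1-ASO, so 87.6% were higher (Clopper-Pearson 95% interval 85.9% to 89.2%). Median usage at the higher sites was 0.739% in 4T1 and 5.17% in 4T1-U1-ASO, and at the lower sites 13.9% and 2.05%. Log2 fold changes in the authors' deposited table were 4.43 for Luc7l2, 4.09 for Tra2a, 3.88 for Sfpq, 3.88 for Ywhaz and 3.68 for Memo1. For lower sites, the authors' deposited table gives -4.27 for Epha2, -4.23 for Tmem167, -3.98 for Rock2, -3.64 for Uchl5, -3.54 for Dancr and -3.40 for Gpr107. Sfpq, a splicing and paraspeckle protein, was used at 11.2% ± 1.16 against 0.540% ± 0.441 in 4T1 (SD, n = 2). Ywhaz and Memo1 had no IPA reads in 4T1, among 11339 and 451 last-exon reads, which allow up to 0.0265% and 0.665%, and were used at 0.362% ± 0.00590 and 7.65% ± 3.01 in 4T1-U1-ASO (SD, n = 2). Epha2, an ephrin receptor kinase, and Gpr107 had no IPA reads in 4T1-U1-ASO, which allows up to 0.164% and 1.08%, against 3.3% ± 0.396 and 11.4% ± 0.688 in 4T1 (SD, n = 2). Rock2 went from 56.6% ± 21.7 to 3.84% ± 0.0571 (SD, n = 2), and its last-exon reads were 16 and 70 in 4T1 and 843 and 887 in 4T1-U1-ASO. Its IPA reads were 41 and 49 against 34 and 35, a log2 change of -0.96 with size factors (adjusted p = 0.00632) and -0.37 with peak-list totals (adjusted p = 0.238, edgeR quasi-likelihood test), so the change lies mostly in the last exon.

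**Figure D3:**
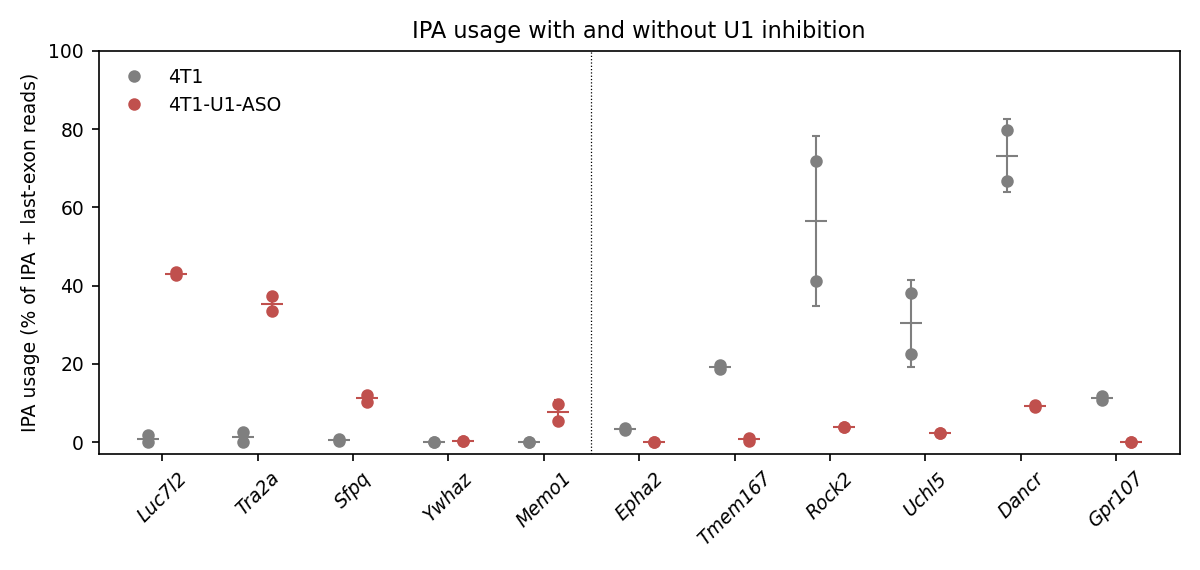
IPA usage in percent, per library with mean ± SD, at 5 sites used more and 6 used less among those with the largest deposited fold changes, in 4T1 and 4T1-U1-ASO (n = 2 each). Luc7l2 rises from 0.893% to 43.0% and Dancr falls from 73.2% to 9.31%.

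A gained site is one used more relative to the last exon, whether or not its own reads rose. Several sites were gained in the same gene in many cases. Anxa3, an annexin, and Chka, choline kinase, had 9 gained sites each, Tra2a 8, Zwint 7, and Luc7l2 and Tpm1 6 each, while 745 genes had 1. Sites moved in both directions in 25 genes, among them Rock2, Epha2 and Hsp90ab1.

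No gene list passed an adjusted p under 0.05 in the U1-ASO table. All 22 SR and hnRNP splicing factors with a site in any table were listed here, against 17.1 expected (two-sided Fisher's exact test, p = 0.00738, adjusted p = 0.155 over the lists). With a higher site only, 21 of the 22 were listed, against 14.8 expected (Fisher's exact test, p = 0.00250, adjusted p = 0.0524), and Rbfox2 was lower. Tra2b rose from 7.98% ± 3.83 to 50.3% ± 0.296, Srsf10 from 13.9% ± 6.35 to 57.0% ± 6.57 and Hnrnpu from 9.59% ± 1.36 to 23.4% ± 1.25 (SD, n = 2). Srsf3 rose from 0.445% ± 0.136 to 12.02% ± 0.494 and Hnrnpl from 0.631% ± 0.256 to 6.37% ± 0.804 (SD, n = 2). All 5 genes of the U1 snRNP list with a site in any table (Luc7l, Luc7l2, Snrpb, Snrpc and Tia1) were listed (expected 3.89 in either direction, exact p = 0.593). All 5 were higher. Luc7l rose from 0.822% ± 0.806 to 6.40% ± 0.626 and Snrpc, a core protein of the U1 particle, from 2.65% ± 1.16 to 10.5% ± 0.315 (SD, n = 2). Of the cleavage and polyadenylation factors, 10 of 11 were listed (expected 8.56, exact p = 0.473), and Pabpn1 was the 1 used less. Cpsf6, a cleavage factor subunit, rose from 0.113% ± 0.160 to 8.81% ± 1.26 and Pabpc1, a poly(A)-binding protein, from 3.70% ± 1.1 to 12.03% ± 0.842 (SD, n = 2).

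Among structural genes, 10 of 11 in the integrin and focal adhesion list had a site (exact p = 0.473). Msn, moesin, rose from 0.225% ± 0.204 to 2.45% ± 0.235 (SD, n = 2), and Pxn, paxillin, was lower. DNA repair genes went both ways, with 7 of 10 listed (exact p = 0.469). Xrcc5, a Ku subunit, and Msh6 were among those higher, and Rad50 fell from 27.9% ± 7.70 to 1.76% ± 2.50 and Smc6 from 18.2% ± 8.05 to 2.07% ± 0.329 (SD, n = 2). Heat shock genes were all listed, 5 of 5 (exact p = 0.593), with Hspd1, a mitochondrial chaperonin, rising from 7.10% ± 1.28 to 24.9% ± 2.45 (SD, n = 2). Tgfb1, a growth factor, fell from 17.9% ± 5.89 to 1.22% ± 1.72 (SD, n = 2).

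Other lists had 5 of 6 elongation factors, 5 of 9 cell cycle genes, 5 of 9 mesenchymal genes, 4 of 6 Wnt, Notch and Hippo genes, 4 of 5 epithelial genes, 3 of 3 drug transport and target genes, 2 of 3 proteases, 2 of 2 TGF-beta genes, 1 of 2 receptor kinases and 1 of 1 interferon genes. The p53 target, fibroblast and matrix, leukocyte and endothelial lists had 0 genes in any table. Over all 5 comparisons and 21 lists, 0 of 105 Fisher's exact tests passed an adjusted p under 0.05, and 1 had an unadjusted p under 0.05. In one direction only, 0 of 210 exact tests passed and 3 had an unadjusted p under 0.05. The background of these tests is mostly made of genes from the U1-ASO table, which leaves little room for enrichment in that table.

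Both parts of the usage ratio were examined. At the 1368 higher sites, reads at the site itself rose in 462 and fell in 16 with the authors' size factors, and in 693 and 5 with peak-list read totals (edgeR quasi-likelihood test). Only the last exon passed, as a fall, at 634 with size factors and 264 with totals, where sites with too few own reads to be tested are included. Last exons of the genes with a gained site fell in 576 of 980 and rose in 63 with the authors' size factors, with a median log2 change of -0.72. With peak-list read totals these numbers were 282, 137 and -0.12. Mean size factors were 0.844 in 4T1 and 1.26 in 4T1-U1-ASO. Last-exon reads of Hnrnpl were 1988 and 2076 in 4T1 and 714 and 630 in 4T1-U1-ASO, a log2 change of -2.20 with size factors and -1.59 with totals. For Hspd1 the values were -2.26 and -1.68, with 56 and 77 IPA reads in 4T1 and 78 and 107 in 4T1-U1-ASO. At the 193 lower sites, reads at the site fell in 122 with size factors and in 91 with totals (edgeR quasi-likelihood test).

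The peak lists showed more distinct peaks in 4T1-U1-ASO. At 1101154 reads on 9 common chromosomes, the 4T1-U1-ASO libraries had 42580 and 41413 peaks and the 4T1 libraries 23879 and 27912. The other libraries had 32492 and 40863 (67NR, the second from the list with 2 blocks), 28297 and 29652 (4T07), and 26206 and 27691 (168FARN). The authors' deposited table has 367 of the 1561 sites at an adjusted p of at most 0.01, and 905 had a peak in both replicates of a group.

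**Figure D4:**
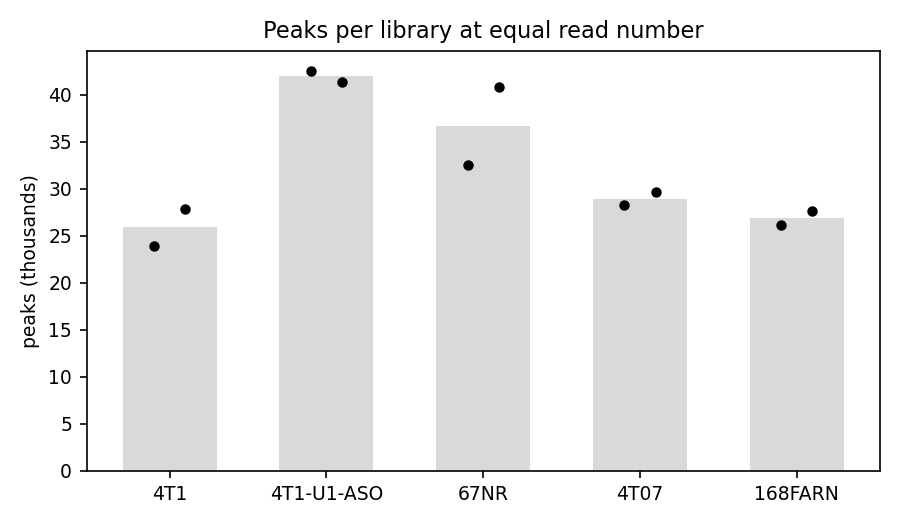
Number of peaks per library at 1101154 reads on the 9 chromosomes that every peak list covers. Bars are means of 2 libraries and points single libraries; the 4T1-U1-ASO libraries have 42580 and 41413 peaks and the 4T1 libraries 23879 and 27912.

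Sites that changed under U1-ASO were compared with those that differ between 4T07 and the non-metastatic lines. With 4T07 against 168FARN, 42 U1-ASO sites overlapped a listed site and 34 had the same direction, with 23.3 expected from the margins (two-sided Fisher's exact test of direction, adjusted p = 0.000218). Single sites in Sfpq, Tra2a and Tulp4 overlapped 2 U1-ASO sites each, and with these counted once 31 of 39 had the same direction (22.4 expected, adjusted p = 0.00124, Fisher's exact test). Matched by gene symbol, 50 of 86 combinations of gene and direction (58.1%) had the same direction, with 36.9 expected (adjusted p = 0.00137, Fisher's exact test). Genes with sites moving both ways under U1-ASO, such as Rock2 and Uchl5, count in both directions here, so this p-value is only approximate. The number shared showed no excess: 25 were lower in both (25.2 expected, adjusted p = 1) and 9 higher in both (45.6 expected, adjusted p = 6.38e-20, Fisher's exact tests). All 25 shared sites lower under U1-ASO were also lower in 4T07, including Rock2, Uchl5, Smarcad1, a chromatin remodeller, and Cflar, a caspase regulator. Smarcad1 fell from 76.5% to 25.6% on average under U1-ASO and was used at 61.4% in 4T07 and 93.9% in 168FARN. Of the 17 shared sites higher under U1-ASO, 9 were higher in 4T07, among them sites in Tra2a, Sfpq and Chka, and 8 lower, among them sites in Tpm1 and Tln1. With 4T07 against 67NR, 18 sites were shared and 8 had the same direction (Fisher's exact test, adjusted p = 0.641). Of these, 7 were lower in both (16.9 expected, adjusted p = 0.0102) and 1 higher in both (25.9 expected, adjusted p = 3.55e-17, Fisher's exact tests), fewer than expected. The background of 2010 sites holds only listed sites, most of them from the U1-ASO table, which favours such deficits.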

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

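The tests of shared-site differences between lines and the tests of explanations in this part were chosen only after the result was seen, except the test in lines without a library in the table, which was chosen after the pattern but before its own result was seen.

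Comparisons of lines that have no common library shared 58 pairs of values, at 45 distinct sites. The deposited log2 fold changes differed in 19 pairs, at 18 distinct sites in 17 genes (z test from the deposited standard errors, Benjamini-Hochberg). In 13 of these pairs the directions were opposite, and since each site passed the authors' threshold in both tables, the z test could hardly miss there and adds nothing to the directions. All values that follow are differences of log2 fold changes in the authors' deposited tables. For 4T1 against 67NR minus 4T07 against 168FARN, opposite directions gave 5.02 for Kcnk2, -5.89 for Abcb10, 3.99 for Prickle2, 3.37 for Rin2, -3.24 for Nav2, 3.10 for Sbno2 and 2.60 for Eif4e2 in the authors' deposited tables. For 4T07 against 67NR minus 4T1 against 168FARN, the authors' deposited tables gave -5.37 for As3mt, -4.41 and -2.96 for 2 sites in St6galnac6, -3.54 for Ptges3, 3.23 for Ddah1 and 3.13 for Auh, again in opposite directions. Sites with the same direction but a different size were Dhx40 (3.40), Camk1d (2.65) and Tpx2 (1.96) in the first pair and Twist2 (-2.30), Dhx40 (-1.98) and Trps1 (1.88) in the second, from the authors' deposited tables. Of these, the difference in size passed on recovered reads only at Camk1d (adjusted p = 0.00774) and Tpx2 (adjusted p = 0.000418) in the first pair (z test of edgeR fold changes). Dhx40 differed by 2.62 there without passing (adjusted p = 0.0529, z test). In the second pair the differences were -0.36 for Twist2, 0.09 for Dhx40 and -1.74 for Trps1 (adjusted p = 0.921, 0.969 and 0.493, z tests), so the deposited differences in size were not found again at these 3 sites. Other sites with the same direction passed on recovered reads but not on deposited values. They were Ldhb, Hip1 and Spint2 in the first pair and Dlk2, Gpr126, Tpx2 and Spint2 in the second (adjusted p from 3.69e-05 to 0.0353, z tests). Kcnk2, a potassium channel, was used at 84.0% in 4T1 and 42.1% in 67NR, and at 66.5% in 4T07 and 93.7% in 168FARN. Abcb10 was used at 0.248% in 4T1, 14.0% in 67NR, 26.6% in 4T07 and 1.58% in 168FARN. The 13 sites with opposite directions do not follow the division into metastatic and non-metastatic lines.

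Most listed sites were used more in the non-metastatic line. Greater depth of those libraries is argued against by 4T07 against 168FARN, whose mean size factors were the closest, 0.993 and 1.04, and where 79.6% of sites were higher in 168FARN (interval 74.9% to 83.9%), and the incomplete peak list of 67NR replicate 2 by both comparisons without 67NR, the lower of which had 75.3% (interval 64.8% to 84.0%). A rise of last-exon transcripts with no fall of intronic reads stays open at most sites: in 4T1 against 168FARN reads at the site fell in 32 of the 64 sites and rose in 3, but selection on the ratio of site to last exon favours sites whose own reads fell, and 23 passed on the last exon alone. Peak-list reads were also compared in lines without a library in the table. They were fewer in the metastatic line at 64.9% (sites of 4T1 against 67NR), 57.3% (4T07 against 168FARN), 54.7% (4T07 against 67NR) and 66.7% (4T1 against 168FARN) of such sites. At sites listed only under U1-ASO the shares were 47.5%, 57.6%, 50.4% and 57.5%. Only the 64.9% (interval 53.2% to 75.5%) lay clear of its counterpart (44.2% to 50.9%). At sites listed as higher in the metastatic line the shares were 57.1%, 40.7%, 57.1% and 50.0%. The 64.9% was not clear of the first of these (interval 37.2% to 75.5%), so together the shares do not decide. The threshold was then divided by all 723887 peaks, to allow for selection among them. By it 42 of 176 sites fell in 4T07 against 67NR and 0 rose. The explanation is argued against at these sites only if the fitted spread holds, as it was estimated on selected sites. Such p-values can vary with the fit: for Tmem167 in 4T1 against 67NR, log2 changes of 2.86 with size factors and 2.81 with totals gave adjusted p = 4.17e-05 and 5.86e-20 (edgeR quasi-likelihood test). In 4T07 against 168FARN 4 fell and 4 rose, and 0 fell in either 4T1 comparison. These 0s do not decide, as the threshold was hardly within reach. Gosr2, with 1 and 0 reads in 4T1 and 81 and 92 in 168FARN, had adjusted p = 1.61e-06 (edgeR quasi-likelihood test). A biological difference of the non-metastatic lines may remain as a hypothesis, but with 2 lines per class it was not tested apart from other differences between lines.

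The 4T1-U1-ASO libraries held more distinct peaks than the 4T1 libraries. Depth is argued against, since at equal read numbers the means differed by 16101 peaks, with 5703.5 as 2 SD of the 4T1 replicates. Scattered background reads as the whole cause are argued against, since peaks with 10 or more reads were also more numerous, by 1909, with 1012.6 as 2 SD. Priming inside A-rich introns of unspliced transcripts could also add peaks. Of the sites with a peak in both replicates of a group, 82.3% were higher in 4T1-U1-ASO. This criterion kept 745 of the 1368 higher sites and 160 of the 193 lower. Among sites with 10 or more recovered reads in a library, 26.96% to 36.28% had no peak in its filtered list in this comparison. In the comparisons of lines the range was 0% to 22.5%. Whether the deposited filter removes A-rich sites is not given in the sources used here, so such priming and the loss of U1 function cannot be told apart.

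Last-exon reads of genes with a gained site were lower in 4T1-U1-ASO. The size of this fall may come from scaling, since its median log2 value was -0.722 with the authors' size factors and -0.123 with peak-list totals. Scaling is argued against as the whole cause of more falls than rises, since with totals 282 last exons still fell and 137 rose. These genes were selected on the ratio of site to last exon, which favours last exons that fell, so a shortening of transcripts was not tested separately.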

How the results depend on the processing

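The tests on recovered reads, the direction tests of shared sites, the count of each site of a second table once, the background of line sites, the shares of sites in the comparisons of lines, the library block and the scaling by peak-list totals were chosen after seeing the data. At a deposited adjusted p of at most 0.01 the sites fell in number to 36 (4T1 against 67NR), 110 (4T07 against 67NR), 36 (4T1 against 168FARN), 138 (4T07 against 168FARN) and 367 (U1-ASO), by construction. With a peak in both replicates of a group, the U1-ASO comparison had 905 deposited sites, and 901 of the recovered-read calls. The share higher in 67NR against 4T07 was 87.27% at adjusted p of at most 0.01, and the share higher under U1-ASO was 85.76% with 1 site per gene and 82.32% with a peak in both replicates; the cause was not tested. Matched by gene symbol, the direction shares were 71.79% (adjusted p = 0.131, Fisher's exact test) and 79.17% (0.0311, exact) for the line pairs and 58.14% (0.00137, exact) for U1-ASO with 4T07 against 168FARN, and 12 genes were lower both under U1-ASO and in 4T07 against 67NR, fewer than the 19.87 expected (0.0740, exact), where by position 7 sites against 16.9 expected had passed as a deficit (0.0102, exact); matching within 50 bp gave the same adjusted p as 1 bp. The direction shares by symbol count a gene with sites moving both ways once per direction, so their p-values are only approximate. Against the sites of the line tables as background, 24 and 11 sites lower in both were fewer than the 46.86 and 21.66 expected (adjusted p = 9.96e-07 and 0.00824, Fisher's exact tests), where the background of all tables gave an excess. On the same background 6 and 4 sites higher in both no longer passed (adjusted p = 0.247 and 0.0882, Fisher's exact tests). Median replicate overlap of peaks was 43.16%, with 29.86% for reciprocal overlap and 64.86% for peaks in the upper part of the read counts. On recovered reads edgeR called 122, 213, 85, 326 and 1557 sites, and no count moved by over 1.5 times with TMM, DESeq2, no filter, the library block or a library left out, where the U1-ASO count ranged from 1212 to 1495. With a replicate block the counts were 122, 213, 85, 325 and 1557. Only sites that the authors had selected on these same libraries entered the fits, and in the main fits every site tested passed. Such counts, and the fits of named sites, could therefore hardly change and do not show stability. The replicate numbers correlated between groups at -0.068 to 0.437 for last exons and -0.030 to 0.221 for IPA reads, so a pairing of replicates by number is not excluded. Of 912 alternative fits of named sites, 907 kept direction and call, 5 lost the call (Sparc 3 times, Prrx1, Ngef) and 0 reversed. A lone library in such a fit is assumed to vary like the other groups. Gene counts, camera and fry, the fit over 10 libraries and distances from gene starts were not run, for want of an annotation on mm9. In simulation of the U1-ASO comparison 7.50% of changes of 1 log2 unit were recovered.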

Other observations

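The tests of both hypotheses in this part were chosen after the data were seen but before their own results were, except that the shared-site test was divided by comparison afterwards, in wording only, and its repeat with each site counted once was chosen only after the result was seen. The genes of the next paragraph were chosen only after the result was seen.

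Ahnak, which encodes a giant scaffold protein under the membrane, had 5 sites lower in 4T07 against 67NR in the authors' deposited table, with log2 fold changes of -1.95, -2.0, -2.03, -1.64 and -2.14. Axl, a receptor kinase linked to mesenchymal states, was lower in 4T07 against both non-metastatic lines. At the site listed in both, its usage was 0.197% ± 0.0836 in 4T07, 0.613% ± 0.0780 in 67NR and 0.592% ± 0.0460 in 168FARN (SD, n = 2). Tpm1 sites went down in the metastatic lines and up under U1-ASO, where 1 of them rose from 0.946% to 4.20%.

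One hypothesis was that U1 activity is weaker in the non-metastatic lines, so that sites gained under U1-ASO would be those used more in these lines. Among sites shared with 4T07 against 168FARN the result was the opposite. Of the 42 U1-ASO sites that overlap a site of that table, 24.2% of the 33 with a site used more in 168FARN were gained under U1-ASO, and 100% of the 9 with a site used more in 4T07 (two-sided Fisher's exact test, p = 5.45e-05). Sites in Sfpq, Tra2a and Tulp4 each overlap 2 U1-ASO sites. With each site of the 168FARN comparison counted once, 39 remained: 7 gained and 0 lower among those used more in 4T07, and 8 gained and 24 lower among those used more in 168FARN (Fisher's exact test, p = 0.000418). Matched by gene symbol, the contrast was smaller: 35 genes were gained and 30 lower among those used more in 168FARN, and 20 gained and 1 lower among those used more in 4T07 (Fisher's exact test, p = 0.000458). These counts are not exclusive, since a gene with sites moving both ways, such as Rock2 or Uchl5, counts as both gained and lower. In 67NR the shares were 50.0% of 14 and 25.0% of 4, and 18 sites were too few to decide (two-sided Fisher's exact test, p = 0.588). Reads at all 613 gained sites on the 9 common chromosomes were not tested. They made up 0.313% and 0.416% of peak-list reads in 168FARN, 0.369% and 0.392% in 4T07, 0.363% and 0.447% in 67NR, and 0.271% and 0.319% in 4T1. The values of 168FARN and 4T07 overlap, so the opposite result holds for the shared sites only. 4T1 reads helped to select these sites, and the second 67NR value comes from the list with 2 blocks.

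Another hypothesis was that in genes with sites moving both ways under U1-ASO the gained site lies upstream of the lost one, as a premature end would. It lay upstream in 10 of 25 genes (40.0%, interval 21.1% to 61.3%, exact binomial p = 0.424), which leaves the question open.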
